A study of Mus musculus with 12 samples.

How the data were processed

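RNA was sequenced from bone-marrow-derived macrophages of C57BL6 mice. Per the labels, bone marrow cells were grown with interleukin-3 and medium conditioned by L-929 cells, a source of colony-stimulating factor 1, over 10 days of differentiation. The macrophages were then left untreated or given interferon gamma (IFNγ) at 0.2, 2 or 20 U/ml for 8 h. The label of the highest dose gives the unit without the volume, and it was read as U/ml like the others. The labels list 12 libraries in 4 groups, 3 per group, and do not say whether the 3 came from separate animals or cultures.

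The authors' processing used TopHat2 2.1.1, Cufflinks 2.1.1 and Cuffdiff 2.1.1 with the mouse build mm10, per the submitters' processing notes. The deposited expression table holds FPKM (fragments per kilobase of transcript, scaled to the size of the library), per the file headers, with 1 value per group. The header of the untreated column names no unit, and its values were read as FPKM because they span the same range as the other 3 columns. Whether each value combines the 3 libraries of its group or comes from 1 of them is not given in the sources used here. The second deposited table is a Cuffdiff comparison of conditions called untreated and treated, with the log2 fold change, a test statistic or score, a p-value and a q-value per gene, per the file headers. It names no dose. Its 2 columns of values per condition could not be matched to a group and were not used.

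Tests with limma on values per library were planned before the data were examined, and they could not be made because the table holds 1 value per group. No p-value, standard deviation or standard error is given for any difference between doses. The rule planned for that case asked for the authors' q-values. It was not applied, because the deposited comparison names no dose and its fold changes had a correlation across genes between -0.0348 and 0.0384 with those at the 3 doses. A fixed rule of size was used instead, with no condition on q, and this was decided after the data were seen.

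Ratios were computed as differences of log2(FPKM + 1), so the pseudocount was 1, and such ratios understate differences of low genes. The table has 46729 entries, of which 22415 were at 0 in all 4 groups. The filter set beforehand, a mean of at least 1 FPKM over the 4 groups, kept 11852. Of these, 272 were listed at 0 in at least 1 group and were left out, a choice made after the data were seen. Abundant genes such as Psap, Lyz2, Ctsb and Fth1 were among them, and an exact 0 can then be a failed estimate. The merged entry of Ctsd was at 0 in all 4 groups and so fell under the filter. In the authors' deposited comparison the entries of Ctsd, Psap, Lyz2 and Ctsb were marked as having too many reads. A 0 in all 4 groups therefore need not mean no expression. The remaining 11580 entries were used for ratios. An entry counted as higher or lower when its log2 ratio was at least 1 in size, which is a 2-fold difference on this scale. Of the 11580 entries, 695 merge genes that overlap, and reads of such genes cannot be told apart.

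The rule for named genes took the 10 largest and 10 smallest ratios for each dose against untreated and 5 of each between doses, with at least 2 FPKM in the higher group. It also took up to 4 members of each of 33 gene lists with the largest ratio in size at 20 U/ml, and 11 genes of the IFNγ pathway and macrophage activation. Some genes taken by the rule are not reported here. Because short RNAs filled much of the ranking at 0.2 U/ml, the rule was repeated without entries whose genes are all under 200 nt, a choice made after the data were seen. Merged entries of a short RNA and a longer gene stayed in. For each list with at least 3 measured entries, the median log2 ratio was set against 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile describes these values only and is not a test. Symbols found in more than 1 entry were left out of lists, and list members with no entry, such as Irf8 and Cyba, were not analysed here. The table also holds 24 gene names turned into dates, which were not used as gene names.

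Gene positions, transcript lengths and GC content came from GENCODE M21 on GRCm38, the assembly behind mm10, and 99.0% of the 11580 entries had a match. Of 10735 single-gene entries with a locus in the deposited comparison, 99.9% overlapped the position in the annotation. The depth of each library is unknown, since FPKM keeps no depth. The low values were checked for steps of whole reads. Among 1661 entries above 0 and under 0.1 FPKM in every group, the most common ratio of 0.2 U/ml to untreated was shared by 30, so no relative depth could be read from them.

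Ratios and lists were run on simulated data for the comparison of 2 U/ml with untreated over 11580 entries. The simulated noise was normal, scaled to the bulk of the observed ratios in 20 expression bins, without the outlying entries of the real data. Of 66 entries changed 8-fold, 93.9% passed the size rule, against 83.6% of 67 changed 3-fold, 5.97% of 67 changed 1.5-fold and 0.0176% of 11380 unchanged entries. These shares hold for that noise only and give no error rate for the real values. Among 200 unchanged lists of 20 entries, 6% lay above the 95th percentile. These lists were drawn at random from the entries that also supply the random lists, so a share near this was fixed in advance. Alternatives were pseudocounts of 0.1 and 0.01, no filter on low values, a mean of at least 5 FPKM, quantile normalization and upper-quartile scaling. Added after the data were seen were entries listed at 0, removal of entries under 200 nt, removal of a smooth trend on GC content and transcript length, and a filter that ignores the 0.2 U/ml group. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.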

Results

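The response of mouse bone-marrow-derived macrophages to IFNγ, the cytokine that activates macrophages against intracellular microbes, was measured by RNA sequencing. The 4 groups were untreated cells and cells given 0.2, 2 or 20 U/ml for 8 h, with 3 libraries each. The deposited values are 1 FPKM per entry and group, so none of the differences has a replicate check. The depth is unknown. Median FPKM over the 11580 entries used was 12.3 in untreated cells, 12.9 at 0.2 U/ml, 12.8 at 2 U/ml and 13.3 at 20 U/ml. Sums of FPKM over all entries differed more, at 769698, 1025970, 783701 and 904993 in the same order. The merged entry of Eef1a1 and Gm26377 made up 5.03% of the sum in untreated cells and 10.8% at 0.2 U/ml.

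The strongest dose, 20 U/ml, was compared with untreated cells to ask which genes differ after IFNγ. Ly6a, a surface antigen encoded on chromosome 15 from 74994877 to 74998031 (GRCm38), was at 1678 FPKM against 18.1 in untreated cells, a log2 ratio of 6.46. Cxcl9, a chemokine that attracts T cells (chromosome 5, 92321347 to 92328079), was at 163 against 1.04 FPKM. Iigp1, an immunity-related GTPase (chromosome 18, 60376027 to 60392634), was at 415 against 5.53 FPKM. Among genes with lower values, Gas6, a ligand of receptors for the uptake of dying cells (chromosome 8, 13465374 to 13494490), was at 19.3 against 171 FPKM. In all, 754 entries were higher and 340 lower by the size rule.

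The other entries ranked highest by the rule were Serpina3g (log2 ratio 6.35), Cnn3 (5.81), Gbp2b (5.77), Socs1 (5.51), Ccl8 (5.47), Serpina3f (5.46) and the short RNA Vaultrc5 (5.49). Lowest were the merged entry of the pseudogene Gm12164 and Gm22751 (-3.44), Gas6 (-3.08), Lyzl4 (-2.78), the long noncoding RNA Gm14461 (-2.70), Ifi27 (-2.41) and Cd24a (-2.40), with the merged entry of Igf2bp1 and Mir3063 (-2.57). With a pseudocount of 0.1 the Igf2bp1 entry was at -5.41 and the Gm12164 entry at -4.56, so this order depends on the pseudocount. The Igf2bp1 entry was at 5.05 FPKM in untreated cells and at 0.00537, 0.00997 and 0.0209 at 0.2, 2 and 20 U/ml. Its ratios at the 3 doses share that 1 untreated value, so they are not separate observations of a fall. The remaining 3 of the 10 lowest were RNAs under 200 nt. Without such short RNAs, Oasl1 (5.42), Cnrip1 (-2.29), Cbr2 (-2.25) and Fabp4 (-2.24) entered the ranking.

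Genes of the IFNγ pathway itself were split between receptor and response. The receptor chains stayed close to untreated values, with Ifngr1 at 44.5 against 53.9 FPKM and Ifngr2 at 41.7 against 37.0. The kinase Jak1 was at 29.7 against 26.9 FPKM and Jak2 at 10.6 against 4.77. Stat2 was higher by a log2 ratio of 2.87, and the feedback inhibitors Socs1 and Socs3 by 5.51 and 2.37. Of 13 measured entries of this list, 8 were higher and 0 lower, with a median log2 ratio of 1.23. Among 12 entries of interferon regulatory and related transcription factors, 8 were higher and 0 lower. Irf7 (4.54), Batf2 (4.49), Irf1 (3.87) and Nlrc5 (3.17) led, and Ciita, the master regulator of MHC class II genes, was at 7.56 against 0.157 FPKM.

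Both families of IFNγ-inducible GTPases, which act against microbes inside cells, were higher throughout. All 8 entries of guanylate-binding proteins were higher at 20 U/ml, with a median of 4.83, led by Gbp2b (5.77), Gbp5 (5.32), Gbp2 (5.24) and Gbp3 (4.87). All 12 entries of immunity-related GTPases were higher, with a median of 4.26, led by Iigp1 (5.99), Gm12250 (5.31), Tgtp2 (5.16) and Gm4951 (4.86). These genes lie in clusters of near-identical copies, so the division of reads between members is uncertain. All 30 antiviral genes were higher as well, with a median of 3.01. Oasl1, an antiviral protein of the oligoadenylate synthetase family, was at 109 against 1.55 FPKM, Ifit2 at 210 against 5.47, Ifit3 at 247 against 6.71 and Isg15 at 942 against 29.4. The medians of these 3 lists lay at percentile 100 of the matched random lists.

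Antigen presentation genes were higher in both classes. In the MHC class I list, 18 of 23 entries were higher and 0 lower, with a median of 2.08. Tap1, part of the peptide transporter, was at 325 against 27.7 FPKM, H2-T24 at 92.3 against 11.2, H2-T23 at 949 against 126 and Tapbpl at 61.2 against 7.56. All 8 MHC class II entries were higher, with a median of 3.83. H2-Ab1 was at 181 against 6.25 FPKM, H2-Aa at 259 against 13.2, H2-DMa at 261 against 13.7, and the entry of the invariant chain Cd74 at 1396 against 65.9. Among 12 co-stimulation and checkpoint entries, 7 were higher, with log2 ratios of 4.18 for Cd40, 3.89 for Cd274 (PD-L1), 3.83 for Slamf8 and 3.43 for Cd86.

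Chemokine genes went both ways. Of 15 chemokine entries, 9 were higher and 3 lower. Cxcl9 (6.32), Ccl8 (5.47), Ccl5 (5.38) and Cxcl10 (5.30) led, and the 3 lower entries, named after their values were seen, were Ccl3 (-1.95), Cxcl2 (-1.50) and Ccl9 (-1.36). Of 11 entries of the list of cytokines, their receptors and binding proteins, 8 were higher and 0 lower, led by the binding protein Il18bp (5.22), the receptor chain Il12rb1 (4.02), Tnfsf10 (2.79) and Il27 (2.66). Complement and Fc receptor entries were higher in 10 of 16 and lower in 1. The merged entry of C2 and Cfb was at 59.0 against 1.85 FPKM, C3 at 192 against 8.35 and Fcgr4 at 396 against 22.3.

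Genes of nitric oxide, oxidant and itaconate production were higher in 5 of 12 entries, with a median of 0.90. Acod1, which makes itaconate, was at 125 against 2.44 FPKM and Ass1, which supplies arginine, at 90.4 against 8.73. Nos2, the inducible nitric oxide synthase, was at 4.88 against 0.0921 FPKM and Slc7a2 at 13.3 against 3.91. Arg1 stayed below the filter, at 0.316 against 0.242 FPKM. Inflammasome and cell death genes were higher in 10 of 21 entries, led by Xaf1 (2.91), Daxx (2.62), Mlkl (2.21) and Casp4 (1.87). Pattern recognition receptors were higher in 9 of 19, led by Tlr9 (3.26), Nod1 (2.59), Tlr3 (1.59) and Marco (1.56).

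Metabolic lists differed in direction. The list of glycolysis and HIF1A had 8 of 19 entries higher and 0 lower. Hk3 was at 473 against 98.5 FPKM, Hk2 at 88.6 against 22.1, Pfkp at 180 against 50.7 and Pfkfb3 at 14.0 against 3.61. The higher entries include Hif1a (1.31) and Vegfa (1.15), while the glycolytic enzymes Gapdh (0.38) and Eno1 (0.27) did not pass. Cholesterol synthesis genes were lower in 7 of 21 and higher in 0, with a median log2 ratio of -0.80 at percentile 0 of the random lists. Idi1 was at 8.82 against 24.4 FPKM, Cyp51 at 6.79 against 17.4 and Sqle at 13.5 against 32.6. In the lipid handling list, Ch25h (4.34) and Abcg1 (1.44) were higher and Fabp4 (-2.24) and Apoe (-1.02) lower, among 23 entries. TCA cycle and respiratory chain genes had 1 of 30 entries higher, Ppargc1b (1.36), and 1 lower, Idh1 (-1.30). Ndufs3 (0.65) and Idh2 (-0.59) came next in size.

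Cell cycle genes were lower in 4 of 29 entries and higher in 1, with a median of -0.22. Mki67, a marker of cycling cells, was at 9.39 against 35.4 FPKM, Ccnb2 at 32.1 against 88.3 and Birc5 at 101 against 229, while Ccnd1, the cyclin of the G1 phase, was at 174 against 64.7. In the list of alternative activation, the ratio of Mrc1, the mannose receptor, was -1.84 from 88.5 FPKM in untreated cells, and Egr2 was at 4.52 against 11.3, while Tgm2 was at 199 against 29.6 and Il4ra at 66.7 against 21.5. Of 20 lysosome and autophagy entries, Ctsc (3.14) and Ctsh (2.54) were higher and Atp6v0d2 (-2.01) and Tfec (-1.22) lower. Adhesion genes had 3 of 15 entries higher, Icam1 (2.63), Itgal (2.29) and Itgb7 (1.68), and 1 lower, Itgb3 (-1.87).

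Iron handling and stress lists stayed near 0 as groups. Among 8 iron entries the exporter Slc40a1 was lower (-1.69), and Cp (1.00, just under the size rule), Slc11a1 (0.86) and Tfrc (-0.58) followed in size. Among 15 immediate early and stress entries, the heat shock genes Hspa1b (2.37) and Hspa1a (2.05) were higher, and Fos (0.96) and Ier3 (-0.95) did not pass. Macrophage identity genes had 1 of 15 entries higher, Fcgr1 (3.39), and 1 lower, Cx3cr1 (-1.85), beside Maf (-0.76) and Cebpb (0.72).

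Markers of most other cell types were near the floor, and osteoclast markers were not. Under 1 FPKM in every group were 12 of 13 T and NK cell markers, 8 of 8 erythroid markers, 9 of 10 mast cell and basophil markers, 9 of 12 stromal and endothelial markers, 7 of 9 dendritic cell markers, 5 of 8 B cell markers, 8 of 13 neutrophil markers and 2 of 8 osteoclast markers, of which Ctsk reached 31.9 and Nfatc1 9.72 FPKM. Markers with a mean of at least 1 FPKM were Cd2 (0.613 FPKM at 20 U/ml against 2.93), Ighm (11.4 against 8.98), Cd79b (1.25 against 1.20), Kdr (2.01 against 1.45), S100a8 (30.4 against 13.3), S100a9 (2.68 against 2.32) and Mmp8 (3.69 against 15.9). Pecam1, an endothelial and leukocyte adhesion gene, was at 3.41 FPKM at 0.2 U/ml against 0.691 in untreated cells and 0.941 at 20 U/ml. Clec9a, a dendritic cell receptor gene, shares an entry with Clec1b, at 47.1 against 1.27 FPKM. Of 5 osteoclast entries, Mmp9 was lower (-1.07), Ctsk was at -0.98, Nfatc1 at 0.23 and Dcstamp at 0.20.

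Of the entries past the size rule at 20 U/ml, 68.9% were higher. Upper-quartile scaling shifted the median ratio of all entries by -0.13, and quantile normalization by -0.08; the former gave 629 higher and 473 lower, or 57.1% higher. At 0.2 U/ml both scalings shifted the median by -0.10. With a pseudocount of 0.1 the count of lower entries was 539.

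**Figure D1:**
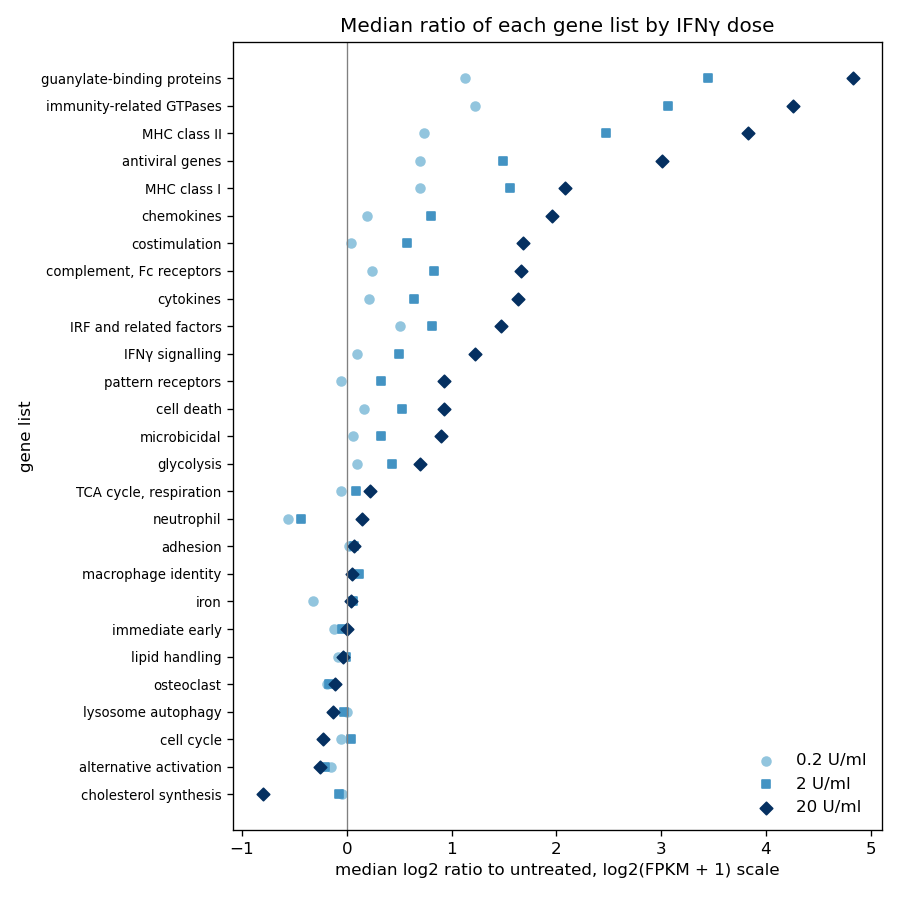
Median log2 ratio to untreated cells, on the log2(FPKM + 1) scale, for each gene list with at least 3 measured entries, 1 list per line. Each point is the median over the entries of a list at 0.2, 2 or 20 U/ml IFNγ, and the guanylate-binding proteins reach 4.83 and cholesterol synthesis -0.80 at 20 U/ml.

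The comparison of 2 U/ml with untreated cells asked what an intermediate dose gives. GTPase genes ranked first: Tgtp2 was at 73.1 against 2.55 FPKM, Iigp1 at 129 against 5.53, Gbp2 at 150 against 8.13 and Gbp2b at 186 against 10.6. Ly6a (3.61), Il18bp (3.61), Gm4951 (3.76), the pseudogene H2-Ea-ps (3.57) and the merged entry of Gbp4, Gbp8 and Gbp9 (3.83) were also among the 10 highest, with the short RNA Mir1195 (3.77). In all, 289 entries were higher and 88 lower. Of the 10 lowest, 7 were RNAs under 200 nt, and the others were the merged entries of Gm12164 and Gm22751 (-3.04), Igf2bp1 and Mir3063 (-2.58) and Trps1 and Mir1907 (-2.17).

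All 8 guanylate-binding entries and all 8 MHC class II entries were higher at 2 U/ml, with medians of 3.44 and 2.48. Among immunity-related GTPases 9 of 12 were higher (median 3.07), among antiviral genes 26 of 30 (1.49) and among MHC class I genes 15 of 23 (1.56). Chemokine entries were higher in 7 of 15 and lower in 1. Cholesterol synthesis genes had 0 of 21 entries past the size rule in either direction, with a median of -0.08, and cell cycle genes 0 of 29. Cd274 was at 34.2 against 6.06 FPKM and Ciita at 2.79 against 0.157. The count of lower entries was 174 with a pseudocount of 0.1, 154 when entries listed at 0 were included and 58 at a mean of at least 5 FPKM.

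**Figure D2:**
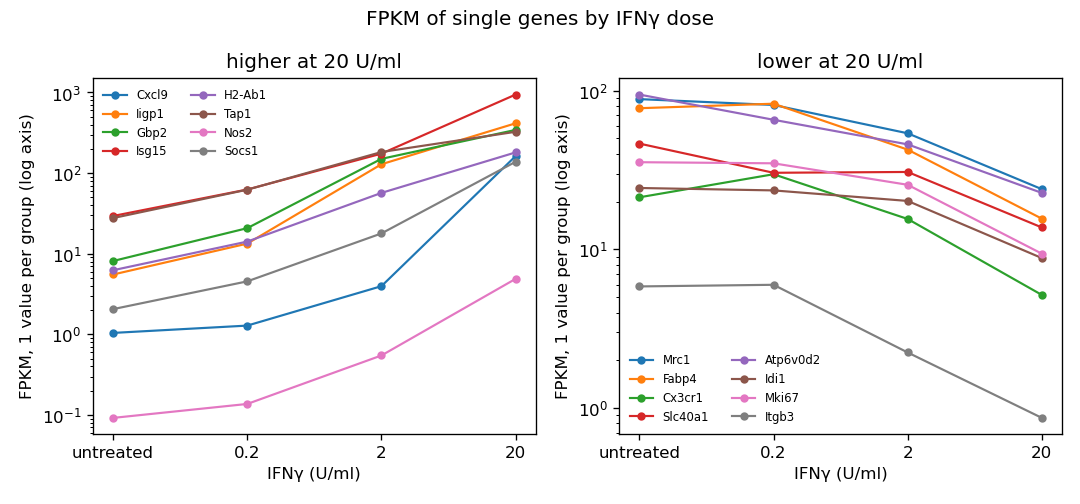
FPKM, 1 value per group on a log axis, of 8 genes with higher values (left) and 8 with lower values (right) at 20 U/ml, by IFNγ dose, chosen from the gene lists after their values were seen. Cxcl9 goes from 3.96 at 2 U/ml to 163 at 20 U/ml, and Mki67 from 35.4 in untreated cells to 9.39 at 20 U/ml.

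The lowest dose, 0.2 U/ml, was compared with untreated cells to ask what a small amount of the cytokine gives. Several GTPase genes were already higher: Gm4951 was at 21.3 against 2.27 FPKM, Tgtp2 at 9.60 against 2.55 and Gbp3 at 11.9 against 3.51. Irf1 was at 89.1 against 34.1 FPKM, while Cxcl9 was at 1.28 against 1.04 and Nos2 at 0.137 against 0.0921. By the size rule 606 entries were higher and 38 lower. Of the 10 highest entries 9 were RNAs under 200 nt, such as Snord15a (5.43), Mir6240 (5.03) and Rny1 (4.45), and of the 10 lowest 7 were.

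Without entries whose genes are all under 200 nt, the merged entry of Gfra4 and Mir6973b (4.94) and Rassf4 (3.61) were among the highest. Noncoding and unannotated entries stood beside them. Merged entries that pair a short RNA with a longer gene stayed in this ranking, and their ratios cannot be assigned to either gene. Gm11032, annotated as protein coding, was at 3.62, with 766 against 61.6 FPKM. Lowest were the merged entries of 4930470G03Rik and Mir1896 (-3.88), Igf2bp1 and Mir3063 (-2.59) and Wdfy2 and Mir8098 (-1.72), and Prss36 was at -1.63. Of the 606 higher entries, 447 were higher at this dose alone, below a log2 ratio of 0.5 at both other doses, and 3 entries were higher in that way at 2 U/ml. Against this background, 5 of 8 guanylate-binding entries (median 1.13), 8 of 12 immunity-related GTPases (1.23), 8 of 23 MHC class I entries (0.70), 4 of 30 antiviral genes (0.69) and 0 of 15 chemokines (0.19) were higher. The immunoproteasome genes Psmb8 (1.51), Psmb9 (1.52) and Psmb10 (1.98), chosen after their values were seen, were at 1.49, 1.52 and 1.86 after removal of the trend on GC content and length. The count of lower entries was 106 when entries listed at 0 were included and 18 without entries under 200 nt.

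The doses were then compared with each other. From 0.2 to 2 U/ml, Iigp1 was higher by a log2 ratio of 3.18, Gbp2b by 2.82, Tgtp2 by 2.80 and Gbp2, without short RNAs in the ranking, by 2.80. The merged entry of 4930470G03Rik and Mir1896 (3.13) and the short RNA Snora41 (2.96) ranked between Iigp1 and Gbp2b. In all, 175 entries were higher and 725 lower at 2 U/ml than at 0.2 U/ml. The lowest were the short RNA Gm23413 (-4.71), the merged entry of Gfra4 and Mir6973b (-4.61) and the mitochondrial tRNA mt-Te (-4.53). The count of higher entries was 275 with a pseudocount of 0.1, 288 with 0.01 and 296 with no filter on low values. The same values at 0.2 U/ml enter this comparison and the one with untreated cells, among them the 447 entries higher at that dose alone.

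From 2 to 20 U/ml, Cxcl9 was higher by a log2 ratio of 5.04, Serpina3g by 4.16, Oasl1 by 3.69 and, without short RNAs, Ccl5 by 3.67. The short RNAs Vaultrc5 (4.50) and Gm22247 (3.69) were also among the 5 highest. Gas6 was lower (-1.85), and so were the short RNA Gm3625 (-2.66) and the merged entries of A330023F24Rik, Mir29b-2 and Mir29c (-2.64), Tnrc6b and Mir5113 (-2.24) and Arid2 and Gm25397 (-2.03). In all, 336 entries were higher and 128 lower. Antiviral genes were higher in 26 of 30 entries at this step, with a median of 1.57, guanylate-binding proteins in 7 of 8 (1.38) and MHC class I genes in 0 of 23 (0.44). Cholesterol synthesis genes were lower in 5 of 21 (-0.61). With no filter on low values 518 were higher. The count of lower entries was 248 with a pseudocount of 0.1 and 203 with entries listed at 0.

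From 0.2 to 20 U/ml, 702 entries were higher and 994 lower. Against untreated cells, 340 were lower at 20 U/ml. The 447 entries higher at 0.2 U/ml alone, with medians of 27.0 FPKM there and 5.47 at 20 U/ml, enter this comparison. The 994 therefore cannot be read as a count of genes lowered by a higher dose. Cxcl9 (6.16), Serpina3g (5.71), Ly6a (5.33), Ccl5 (5.21) and Serpina3f (4.97) were highest. Of the 5 lowest, 4 were RNAs under 200 nt, such as Gm26225 (-4.86), and the fifth was the merged entry of A330023F24Rik, Mir29b-2 and Mir29c (-4.39).

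**Figure D3:**
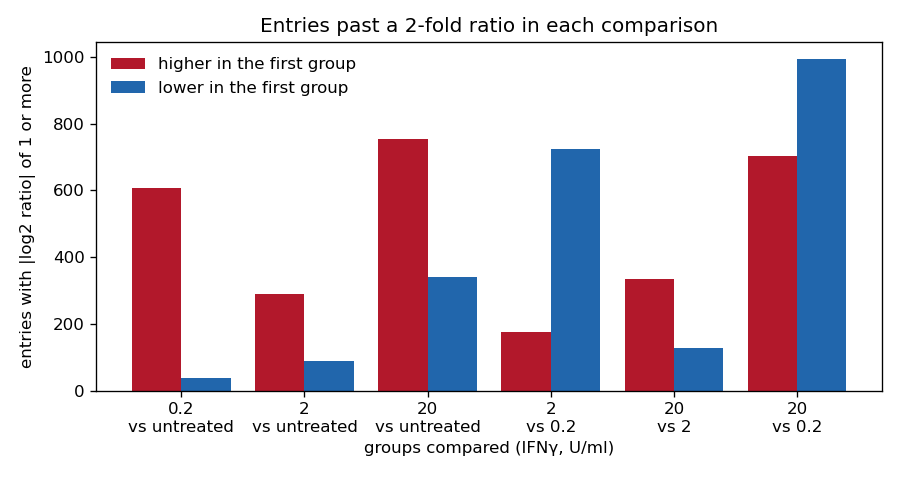
Number of entries, of 11580, with a log2 ratio of at least 1 in size in each of the 6 comparisons (horizontal axis, IFNγ in U/ml). Red bars are entries higher in the first group named and blue bars entries lower in it. They stand at 754 and 340 for 20 U/ml against untreated cells and 175 and 725 for 2 against 0.2 U/ml. Every comparison with 0.2 U/ml includes the 447 entries higher at that dose alone.

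Of the 754 entries higher at 20 U/ml, 99 were already higher by the size rule at 0.2 U/ml and 268 at 2 U/ml. Without entries whose genes are all under 200 nt, these numbers were 79 and 251 of 715. Both dose steps passed the rule for 91 entries, the step from 0.2 to 2 U/ml alone for 47, the step from 2 to 20 U/ml alone for 210 and neither for 406. Values followed the order of the doses in 478 of the 754 entries, and in 164 of the 340 lower at 20 U/ml. Among the 754 higher entries, the median fraction of the 20 U/ml log2 ratio reached was 0.146 at 0.2 U/ml and 0.461 at 2 U/ml, and among the 340 lower entries it was 0.0919 and 0.408. These entries were chosen by their 20 U/ml ratio, which is also the divisor. Noise that makes this ratio larger in size therefore makes the fraction smaller. Both ratios also share the untreated value. Over only those list entries that were higher at 20 U/ml, guanylate-binding proteins reached a median of 0.708 at 2 U/ml, immunity-related GTPases 0.680, MHC class I genes 0.735, MHC class II genes 0.645, antiviral genes 0.514 and chemokines 0.413.

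Responses at 2 and 20 U/ml shared 268 higher and 44 lower entries. Independent lists of these sizes would share 18.8 and 2.58. Simulated unchanged groups with 1 untreated group in common shared 2.05 and 2.02. They were normal noise of equal spread in every group, scaled to the bulk of the 0.2 U/ml ratios in 20 expression bins. Such noise lacks the outlying entries of these data. Equal spread and the shared group set its correlation at 0.499 whatever the data, so the simulated values give no bound here. The correlation of the log2 ratios across genes, which are not independent replicates, was 0.805 against 0.499 simulated, and the covariance 0.255 against 0.0510. For 0.2 and 20 U/ml, 99 higher and 14 lower entries were shared, against 39.5 and 1.12 for independent lists, with a correlation of 0.190 against 0.499 simulated and a covariance of 0.0713. For 0.2 and 2 U/ml, 68 and 12 were shared, against 15.1 and 0.289, with a correlation of 0.230 against 0.499 simulated. The covariance was 0.0504. The simulated 0.0510 was scaled to the 0.2 U/ml ratios themselves, so no conclusion is drawn from their closeness. These pairs share the untreated values, which could not be divided. The comparisons of 0.2 U/ml with untreated cells and of 20 with 2 U/ml share no group. They shared 64 higher and 3 lower entries, against 17.6 and 0.420 for independent lists, and their correlation across genes was 0.0877.

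The authors' deposited table of treated against untreated cells, which names no dose, was set beside the ratios above. Across 10793 entries, which are not independent replicates, the log2 fold changes in the authors' deposited table had correlations of -0.0348, -0.0192 and 0.0384 with the ratios at 0.2, 2 and 20 U/ml.

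**Figure D4:**
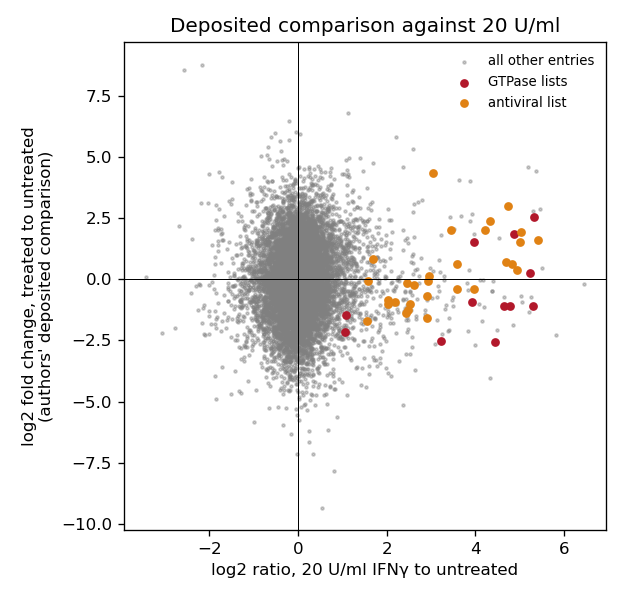
Log2 fold change in the authors' deposited table (vertical axis) against the log2 ratio of 20 U/ml IFNγ to untreated cells (horizontal axis), 1 point per entry. GTPase entries (red) and antiviral entries (orange) lie to the right at 20 U/ml and on both sides of 0 in the authors' deposited table. The median there was -1.08 for 12 GTPase entries and -0.05 for 29 antiviral entries. The GTPase families differed, with 5 guanylate-binding entries at a median of 1.53 and 7 immunity-related GTPases at -1.47.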

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

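The tests of the deposited comparison and of intron length were chosen only after the result was seen. The authors' deposited table of treated against untreated cells, not used in the comparisons between doses, lists 8861 genes with q under 0.05, of which 4516 were higher and 4345 lower in treated cells. Its largest correlation across genes with the ratios at a dose was 0.0384, which argues against a treated condition that is one of the 3 dose groups. The smallest was -0.0348, where swapped conditions would need a clearly negative value. An earlier test of a swap, the median log2 fold change of 12 GTPase entries in the authors' deposited table, gave -1.08. That lay between its bounds, and the test was replaced after that was seen. The median mixed 5 guanylate-binding entries at a median of 1.53 with 7 immunity-related GTPases at -1.47. Another experiment remains a candidate source, which was not tested, and no biological explanation was tested.

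In the 0.2 U/ml group, 447 entries were higher at that dose alone, with a median of 27.0 FPKM against 7.90 in untreated cells. After removal of a smooth trend on GC content and transcript length, 87.8% of the 435 with annotation stayed past the size rule. This argues against that shared trend as the whole cause. The trend was fitted over all annotated entries used, so an effect of GC content or length limited to some entries is not covered. After upper-quartile scaling, a shift of only -0.10, 81.9% of the 447 stayed past the size rule. A single scaling factor would move all entries alike, and the median log2 ratio of the 11580 entries at 0.2 U/ml was 0.00, which argues against it. Unspliced RNA or DNA stays open: a first test, the rank correlation of the ratio with intron length over all protein-coding entries, covered a wider set than these entries and gave -0.0950, which counted against it, and a second on the 252 protein-coding ones, chosen after the first was seen, gave a median of 21802 nt at percentile 99.95 of random lists not matched on transcript length, which was 4088 nt against 3362 nt in all protein-coding entries. A transcript under 300 nt was annotated for 12.7% of the 252 protein-coding entries, against a median of 9.52% in random matched lists. Most of these entries have none, which argues against very short annotated transcripts as the whole cause for them. A part in the pattern stays open, since the share lay at percentile 94.6, between the bounds set beforehand. So does an effect of the low dose, because each group has 1 value.

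The order of entries in the expression table runs through the genome 8 times. The blocks may be the combinations of the authors' own calls at the 3 doses: in 6 of the 6 blocks tested, the doses of the supposed combination had the larger median ratios. The block placed as called at 0.2 U/ml alone holds 417 entries, with median log2 ratios in size of 1.04, 0.11 and 0.15 at 0.2, 2 and 20 U/ml. The supposed calls were not used.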

How the results depend on the processing

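No paired analysis was possible because the table holds 1 value per group, and for the same reason the replicate block, leaving out replicates, fits of 2 groups, eBayes variants, count tools, adjusted p thresholds and list tests with an estimated correlation were not run. The authors' q-values were not used as an alternative, since their comparison names no dose. Counts were held to a factor of 1.5, and so were single ratios and list medians, as a 1.5-fold difference and not 1.5 units of log2. Of the recomputed values, 101 counts stayed within it and 22 moved, 725 list medians stayed and 4 moved, and 4918 ratios of named entries stayed and 131 moved, and none of the ratios or medians past the size rule changed sign. Of the moved ratios, 57 moved with a pseudocount of 0.1 and 72 with 0.01, all to a larger size, since a smaller pseudocount understates differences of low genes less, and 2 with the GC and length trend removed, mt-Ty and mt-Te at 0.2 U/ml. At 20 U/ml with a pseudocount of 0.1, Serpina3g was at 7.31, Cxcl9 at 7.15, Serpina3f at 6.68, Il12rb1 at 5.35, Ciita at 4.90, Nos2 at 4.70, Tnfsf10 at 4.62 and Tlr9 at 4.52, and with 0.01 Cp was at 1.65. The merged entry of Igf2bp1 and Mir3063 at 0.2 U/ml was at -5.61 with a pseudocount of 0.1 and -8.36 with 0.01. These ratios set 0.00537 FPKM at 0.2 U/ml against 5.05 in untreated cells. The 4 medians that moved, at 20 U/ml, were guanylate-binding proteins (5.48) and immunity-related GTPases (5.01) with a pseudocount of 0.01, and chemokines (2.60) and co-stimulation (2.30) at a mean of at least 5 FPKM. The counts that moved were these, and the cause was not tested. With a pseudocount of 0.1, lower entries numbered 71 at 0.2, 174 at 2 and 539 at 20 U/ml against untreated, 248 from 2 to 20 U/ml, and higher entries 275 from 0.2 to 2 U/ml. With 0.01 they were 76, 192, 572, 276 and 288. With no filter on low values, lower entries were 147 at 0.2 and 193 at 2 U/ml, higher entries from 0.2 to 2 U/ml 296, and higher and lower from 2 to 20 U/ml 518 and 248. A mean of at least 5 FPKM gave 24 lower at 0.2 and 58 at 2 U/ml, with fewer entries tested. Chosen after seeing the data: with entries listed at 0, lower entries were 106 at 0.2 U/ml, 154 at 2 U/ml and 203 from 2 to 20 U/ml; without entries under 200 nt 18 and with the GC and length trend removed 67 were lower at 0.2 U/ml. Quantile normalization and upper-quartile scaling moved no count past the factor. Depth is unknown and sets no interval.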

Other observations

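The tests in this part were chosen only after the result was seen, and the genes named from the deposited comparison after their values were seen. In the authors' deposited table, whose dose is not named, the log2 fold change was 6.03 for Dusp1, 5.99 for Osm and 5.26 for Klf4, all higher in treated cells. In the authors' deposited table, Slc7a11, the cystine transporter, had a log2 fold change of 5.84 and Gclc, an enzyme of glutathione synthesis, 5.10. Of the immediate early list, 15 of 15 entries were at 1 or more in the authors' deposited table, with a median of 2.65. Cholesterol synthesis genes in the authors' deposited table were at -1 or less in 17 of 21 entries, with a median of -2.26, and Dhcr7 was at -4.14. Of 29 cell cycle entries in the authors' deposited table, 14 were at -1 or less and 2 at 1 or more, with a median of -0.96. Mcm2, of the replication helicase, was at -5.13 and Ccnd1 at -4.30. MHC class I entries were at -1 or less in 14 of 22 and at 1 or more in 1. For MHC class II these were 4 and 0 of 7, and for alternative activation 3 and 6 of 10. Changes were widespread there, with q under 0.05 for 8861 of 12854 tested genes, and no share over all entries was computed.

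In the dose table, GTPase genes may reach a larger part of their 20 U/ml ratio at 2 U/ml than antiviral genes. The median fraction of the 20 U/ml log2 ratio reached at 2 U/ml was 0.696 for 20 GTPase entries and 0.514 for 30 antiviral entries, a difference of 0.182. At 0.2 U/ml the medians were close, at 0.223 for guanylate-binding proteins, 0.283 for immunity-related GTPases and 0.213 for antiviral genes. The difference at 2 U/ml lay between 0.173 and 0.195 with other pseudocounts and scalings. Genes are not replicates and each dose has 1 value, so no p-value is given, and the difference describes these values only.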
